A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

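Total RNA of a hog1 deletion strain treated with Congo Red and of the untreated part of the same culture was compared on 4 two-channel arrays. The labels give the RNA in each channel, and name no dyes. Replicate numbers were taken from the array titles. The deposited values are log2 ratios of the channels of an array, per spot, as the series value table holds them. That the scale is base 2 was read from the values: on arrays 1 to 3, 59, 58 and 36 values lie within 0.00011 of the base-2 logarithm of a ratio of unequal whole numbers up to 10, against at most 6 for the natural and at most 10 for the base-10 logarithm. Array 4, given to 2 decimals, cannot be read this way, and its SD of 0.95 over spots is like that of the others (0.95 to 0.96). The scanner, background correction, normalization, spot filter and numerator of the ratio are not given in the sources used here. Median deposited log2 ratios were 0.01, -0.13, 0.22 and 0.07 on arrays 1 to 4, so the spots were not centred on their median. The other arrays are given to 4 decimals. Signal intensities were not analysed here, so spots close to the background or at the scanner's ceiling could not be set apart. All spots of 8 genes (CCW12, CDC19, ENO1, ENO2, FBA1, PGK1, TDH2 and TDH3) lay within 0.005 of the ratio of TDH2 on at least 1 array.

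The table has 896 spots. Through the platform's annotation, which is old, 724 spots have 1 gene, 10 have several and 162 have no name here. The named spots stand for 353 genes, and all 353 matched the R64 gene table, which was used only for names and gene order. Spots of one gene were averaged on each array, mostly 2 spots a gene. A value was present on 4 arrays for 328 genes and on 3 arrays for 20, and the 5 genes with fewer were not tested. Between 53 and 73 spots per array had no value. How specific the probes are for members of gene families is not given in the sources used here.

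The rule for direction was fixed before the data were examined: values were kept as deposited if arrays of opposite channel order correlated on average above 0 over all spots, and a mean between -0.3 and 0.3 counted as unsettled, with the other turning given as well. The mean was 0.15.

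Each gene's log2 ratio was tested against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the 348 genes and a threshold of 0.05. A second model added a coefficient for channel order, which is 1 for arrays 1 and 3 and -1 for arrays 2 and 4. The 17 gene lists were written from general knowledge before the data were examined. The chip held only part of several lists, such as 6 of 30 general stress, 5 of 31 polarity and actin and 10 of 45 N-glycosylation genes. The 14 lists with at least 5 genes valued on all arrays were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Named genes were the 12 with the largest rise and the 8 with the largest fall among those past the threshold with one sign on all measured arrays, up to 2 more members of each list past the list test, and HOG1, SLT2, RLM1, CRH1, PIR3, CWP1, CHS3, FKS1, GSC2, GFA1, PST1 and ACT1. Genes named outside this rule are said to be so. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

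The gene test was tested on simulated data for the 328 genes with 4 values, with 60 changed genes in each of 50 simulations. It recovered 41.9% of genes changed 1.5-fold, 75.1% of those changed 2-fold and 93.4% of those changed 4-fold, and 1.03% of its calls were unchanged genes. The simulated noise was independent between arrays and genes, the turning was taken as right, and rises and falls were equally likely. These gene rates are therefore not the error rates of the gene calls below. A shifted list was called by camera in 100% of the simulations with either correlation, and an unshifted list in 8% with the preset and 0% with the estimated correlation. These list rates use an unadjusted p under 0.05 for a single list of independently simulated genes. They do not describe the list calls below, which were adjusted over all tested lists and whose genes may be correlated.

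Alternatives tried were centring and scaling of the arrays, the other turning, a term for channel order, averaging of array pairs as if they were technical swaps, array weights, robust variance estimation, other limits on missing values, spots tested singly, thresholds on fold, and each array left out in turn. Leaving out genes with discordant duplicate spots (SD over 0.5 on any array), leaving out the 8 genes with the repeated ratio and combining the channel order term with an estimated correlation were chosen after seeing the data.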

Results

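Transcript ratios were measured in Saccharomyces cerevisiae BY4741 lacking HOG1, the gene of the MAP kinase that ends the high osmolarity pathway. A culture grown at 24 °C in rich medium was split, and one part received 30 µg/ml Congo Red, a dye that binds chitin and glucan and disturbs the assembly of the cell wall. RNA was collected after 4 h from the treated and the untreated part and hybridised together on a dedicated microarray of cell wall genes, with 4 arrays in all. The treated RNA was in channel 2 on arrays 1 and 3 and in channel 1 on arrays 2 and 4. The comparison asks which of the spotted genes differed between treated and untreated cells in the absence of Hog1. No strain with an intact HOG1 was analysed here, so no difference between strains was measured. Of 353 named genes, 348 had values on at least 3 arrays and were tested. The number of arrays limits the precision, since 4 arrays cannot give an exact two-sided sign-flip p under 0.125 for a single gene. Whether the arrays came from separate cultures is not given in the sources used here, and the p-values then measure only the spread between these arrays, which may be technical.

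The numerator of the ratios is not given in the sources used here. It was assumed, before the data were examined, to be the Congo Red RNA, and no test here bears on it. The direction is called likely only because genes known to be induced by cell wall stress are then higher, a reason added after the values were seen, so their direction is no independent finding. Values were kept as deposited, as if already turned to one direction, because arrays of opposite channel order correlated above 0, which bears on the turning and not on the numerator. If the ratio ran the other way, each rise below would be a fall and each fall a rise. Over all spots that correlation was on average 0.15 (across spots, which are not independent replicates), a value too low to settle the turning by the rule fixed beforehand, which asked for 0.3. Over named genes it was 0.35, and over those with values on all 4 arrays 0.40, both above that bound, but the rule was set on all spots. With arrays 2 and 4 turned, limma called 0 genes at an adjusted p under 0.05, and 33 had an unadjusted p under 0.05. That fit had no term for channel order, so any ratio shared by the 4 arrays entered its spread. In the model with such a term, the treatment under the other turning is the channel order coefficient. It passed for 23 genes (limma adjusted p under 0.05), against 121 for the treatment as deposited in that model.

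HOG1 (YLR113W), deleted in the RNA of both channels, had log2 ratios of 1.43, -1.73, -0.23 and 1.25 on arrays 1 to 4 and did not pass the test. The position of its probe relative to the deleted part is not given in the sources used here, so these ratios check neither the deletion nor a level. ACT1 (YFL039C), the actin gene spotted 16 times, had a mean log2 ratio of 0.06 ± 0.13 (SD, n = 4) and did not pass either.

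After Congo Red, 16 of 23 genes known to answer to cell wall stress were higher. The tested gene with the largest mean change was CWP1 (YKL096W), which encodes a mannoprotein of the wall, 9.98-fold higher (log2 3.32 ± 0.49, SD, n = 4; limma adjusted p = 0.00148). CRG1 (YHR209W), a methyltransferase gene, rose 9.78-fold with little spread (log2 3.29 ± 0.08, n = 4; limma adjusted p = 0.000148). YPS3, a yapsin protease of the cell surface, rose 5.38-fold (log2 2.43 ± 0.52), PRM5, a membrane protein gene, 4.56-fold (2.19 ± 0.23), and KTR2, a mannosyltransferase gene, 4.44-fold (2.15 ± 0.27). In all, 72 of the 348 genes passed at a limma adjusted p under 0.05, 59 higher and 13 lower, and 113 had an unadjusted p under 0.05. Each of the 72 had the same sign on every array that measured it, as did 146 of the 348 tested genes with the 72 included. The test favours such genes, so the shared sign adds no separate support. A mean change of at least 1.5-fold was reached by 54 higher and 9 lower genes, and of at least 2-fold by 30 and 2. With the arrays centred on their medians and scaled, 63 were higher and 30 lower, and with a term for channel order 87 and 34. The added calls of that model include MET17 (log2 1.40, adjusted p = 0.00136), a gene deleted in BY4741 whose probe position is likewise not given, chosen after its values were seen. Leaving out array 3 left 33 higher and 5 lower.

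**Figure D1:**
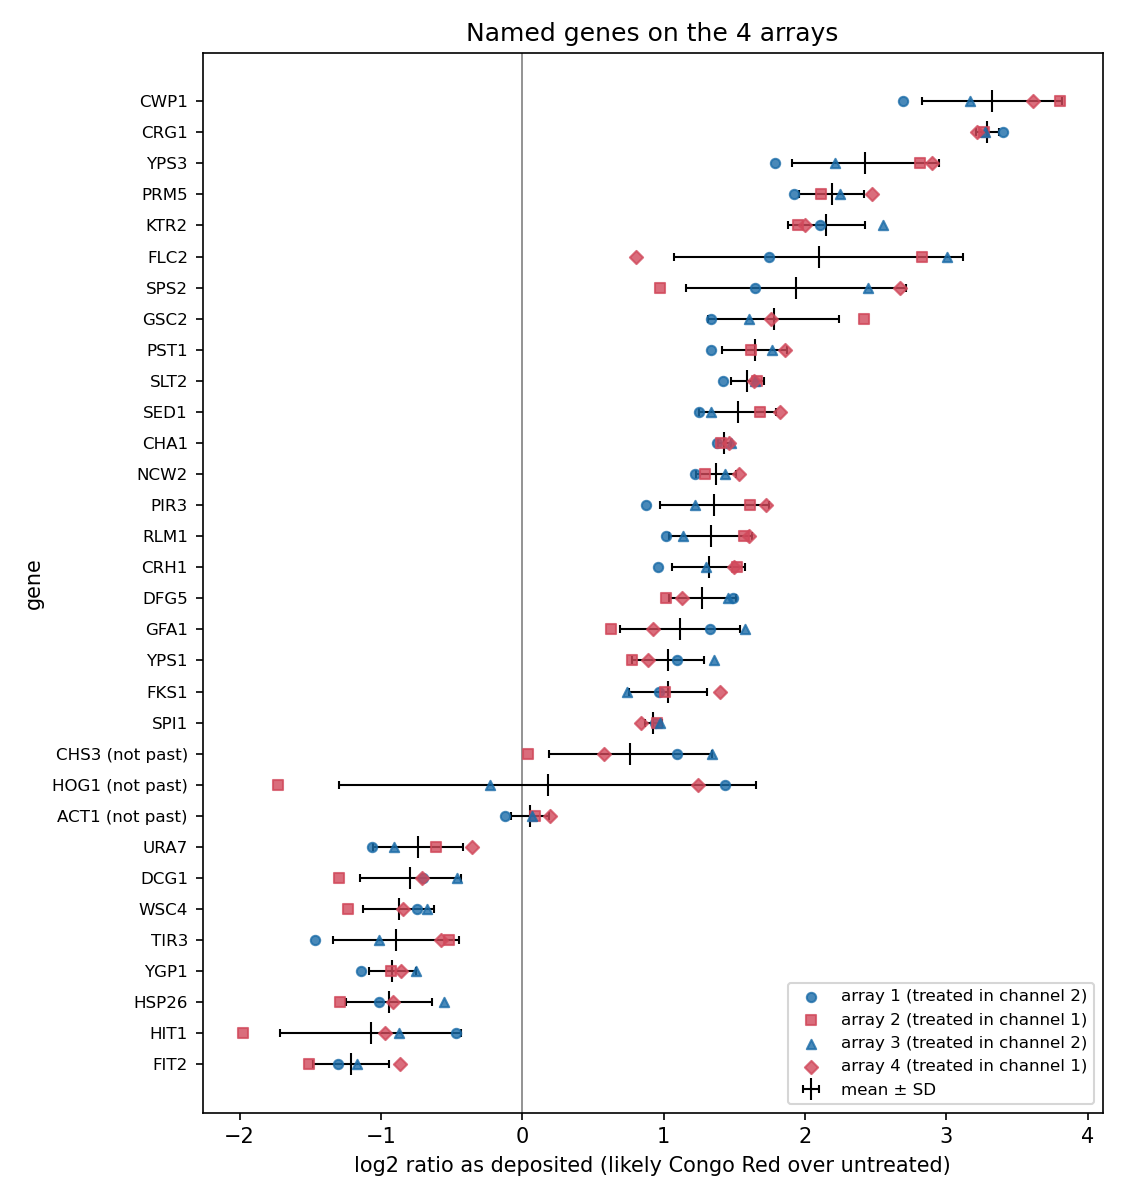
Log2 ratio (x axis, as deposited and likely Congo Red over untreated) of each named gene (y axis) on the 4 arrays, with bars for the mean ± SD. CWP1 and CRG1 lie highest, at means of 3.32 and 3.29, FIT2 lies lowest at -1.21, and the arrays of HOG1 spread on both sides of 0.

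The cell wall integrity response list, genes known to be induced through the MAP kinase Slt2, stood out most. Of its 23 tested genes 16 were higher and 0 lower, or 20 higher when adjusted over the list alone. The kinase gene itself, SLT2 (YHR030C), rose 3.01-fold (log2 1.59 ± 0.12, n = 4), and RLM1 (YPL089C), which encodes its transcription factor, rose 2.52-fold (1.33 ± 0.30). Among the wall proteins of the list, PST1 rose 3.13-fold, SED1 2.87-fold, NCW2 2.58-fold, PIR3 2.56-fold and DFG5 2.42-fold. The 22 members with values on all arrays had a mean log2 ratio of 1.17, against 0.10 for the other genes (camera, preset correlation, adjusted p = 1.4e-10). The call was lost with an estimated correlation (camera adjusted p = 0.46, unadjusted p = 0.033). In fry, which tests against 0 and makes no comparison with other genes, the list was above 0 (adjusted p = 0.00359). CHS3, the main chitin synthase, had a log2 ratio of 0.76 ± 0.58 and did not pass (limma adjusted p = 0.0942), although it did with a term for channel order (adjusted p = 0.00784).

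Genes for the synthesis of the wall polymers were also among those higher. The β-1,3-glucan list shares GSC2 and BGL2 of its higher genes with the integrity response list. Of its 15 genes 6 rose and 0 fell (7 and 0 adjusted over the list alone). Among them were GSC2 (YGR032W, also known as FKS2) and FKS1 (YLR342W), genes for alternative forms of the catalytic subunit of glucan synthase. GSC2 was 3.43-fold higher (log2 1.78 ± 0.46) and FKS1 2.04-fold higher (1.03 ± 0.28). The glucanase genes EXG2, BGL2 and EXG1 and the glucan-remodelling gene GAS2 were higher as well. FKS1 and GSC2 are related in sequence, and how far their probes tell them apart is not given in the sources used here. The chitin list shares CRH1 and GFA1 of its higher genes with the integrity response list. It had 5 of 10 genes higher and 0 lower (6 and 0 adjusted over the list alone). They were CRH1 (YGR189C), which links chitin to glucan, 2.49-fold higher (log2 1.32 ± 0.26), GFA1 (YKL104C) and PCM1, enzymes of the pathway to the chitin precursor, 2.16-fold (1.11 ± 0.42) and 2.22-fold (1.15 ± 0.34), with the call of GFA1 lost without array 1 or 3, CHS7, needed for the export of Chs3, and CHS1. GNA1 and QRI1, further enzymes of the pathway to the chitin precursor, had log2 ratios of -0.30 ± 0.31 and -0.42 ± 0.54 and did not pass. PCM1, CHS7, CHS1, GNA1, QRI1, EXG2, BGL2, EXG1 and GAS2 lie outside the rule for named genes and were chosen after their values were seen. As lists, neither passed camera (adjusted p = 0.0561 for β-1,3-glucan and 0.148 for chitin). The β-1,3-glucan list passed with a term for channel order (adjusted p = 0.0383), after centring (0.0426) or scaling (0.0393), with spots tested singly (0.0164) and without array 2 (0.0398), but not with an estimated correlation (adjusted p = 0.71). The chitin list passed with spots tested singly (adjusted p = 0.0337), and had adjusted p = 0.69 with an estimated correlation. With spots tested singly, duplicate spots of a gene counted as separate members of a list, so passing there adds no independent support. Tested against 0 with fry, which makes no comparison with other genes, both lists were above it (adjusted p = 0.0204 and 0.00359).

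Transcripts of genes for proteins attached to the wall or membrane by a GPI anchor changed in both directions. Of 38 tested genes 12 were higher and 3 lower (14 and 3 adjusted over the list alone), and 8 of the 12 also belong to the integrity response list. SPS2, best known from sporulation, rose 3.82-fold (log2 1.93 ± 0.78; the call was lost without array 3), YPS1 2.04-fold (1.03 ± 0.26) and SPI1 1.90-fold (0.93 ± 0.06). FIT2, a mannoprotein gene of iron uptake, fell 2.32-fold (log2 -1.21 ± 0.27), the cold-shock type mannoprotein gene TIR3 1.86-fold (-0.89 ± 0.44), a call lost without array 1, 3 or 4, and FIT3, named after its values were seen, had a log2 ratio of -0.57 ± 0.24. The list had a mean of 0.53 over 36 genes, against 0.12 for the others (camera adjusted p = 0.0195, but adjusted p = 0.71 with an estimated correlation). It missed the threshold once genes with fewer than 4 values entered (adjusted p = 0.0574). In fry, against 0, the list was above it (adjusted p = 0.0204).

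**Figure D2:**
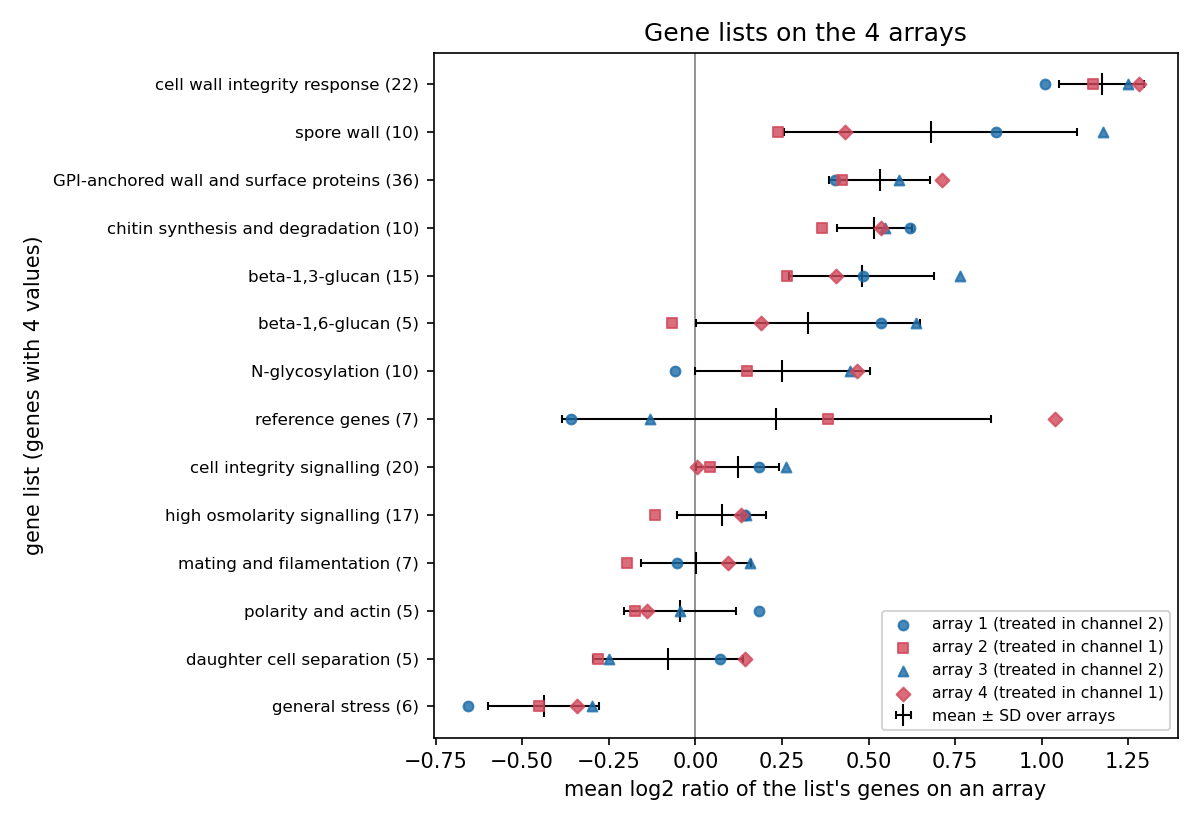
Mean log2 ratio on each array (x axis) of the genes of each list with values on all 4 arrays (y axis, number of genes in brackets), with bars for the mean ± SD over arrays. The cell wall integrity response lies between 1.01 and 1.28 on every array, and the general stress list between -0.66 and -0.30.

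Called members of the cell integrity signalling pathway went both ways. Of 21 tested genes of its list 4 were higher (SLT2, RLM1, the phosphatase gene MSG5 and the transcription factor gene SWI4) and 2 lower (adjusted over the list alone, also 4 and 2). SLT2 and RLM1 also belong to the integrity response list. The lower genes were WSC4 (YHL028W), 1.83-fold lower (log2 -0.88 ± 0.25), and MID2, with a log2 ratio of -0.44 ± 0.11. Both encode membrane proteins of the sensor families. MSG5, SWI4 and MID2 were named after their values were seen. The list did not differ from the other genes (camera adjusted p = 0.712), with a mean of 0.12 against 0.17 for the others, while fry placed it above 0 (adjusted p = 0.0489). In the high osmolarity signalling list, 1 of 17 genes was higher and 0 lower, the same adjusted over the list alone. That gene was SSK22, a kinase gene of the branch that leads to Hog1, 2.37-fold higher (log2 1.24 ± 0.14, limma adjusted p = 0.00333), named after its values were seen. The list, which includes the deleted gene HOG1, had camera adjusted p = 0.712.

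The general stress list leaned downwards. Of the 30 genes written into it, only 6 were on the chip. Of these 6, all tested, 0 were higher and 2 lower (0 and 3 adjusted over the list alone). HSP12, named after its values were seen, had a log2 ratio of 0.38 ± 0.54 and did not pass. HSP26, a small heat shock protein gene, fell 1.92-fold (log2 -0.94 ± 0.30, not past without array 1) and YGP1, a secreted glycoprotein gene, fell 1.89-fold (-0.92 ± 0.17). The list's mean was -0.44 against 0.18 for the other genes (camera adjusted p = 0.0383, but adjusted p = 0.69 with an estimated correlation), and centring the arrays also ended the call (adjusted p = 0.0540). In fry, against 0, the list was below it (adjusted p = 0.0204).

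Of the remaining lists with enough genes for camera, none passed with the values and model used above. The spore wall list had 4 of 11 genes higher (SPS2, GSC2, GAS2 and SPS22) and 0 lower. GSC2 also belongs to the integrity response list. The spore wall list had camera adjusted p = 0.126. It passed with a term for channel order (adjusted p = 0.0383), with spots tested singly (0.0234) and without array 2 (0.0398), but not with an estimated correlation (adjusted p = 0.71). Where spots were tested singly, duplicate spots again counted as separate members. Without genes of discordant duplicate spots, a filter chosen after seeing the data, its mean went from 0.68 to 0.41 (adjusted p = 0.643). In fry, against 0, it had adjusted p = 0.0489. SPS22 resembles SPS2 in sequence, and whether their probes tell them apart is not given in the sources used here. N-glycosylation had 1 of 10 genes higher, the mannosyltransferase gene ALG9, which was also the single gene higher of the 7 in the reference gene list. Of these 7, the glycolytic genes TDH2, TDH3, ENO1, ENO2 and PGK1 carried a ratio that repeated across genes within 0.005 on at least 1 array, such as -0.65 on array 1, so their ratios may not measure their transcripts. β-1,6-glucan, mating and filamentation, daughter cell separation, and polarity and actin had 0 genes called among 5, 8, 5 and 5 tested (limma), and 1, 0, 1 and 0 at an unadjusted p under 0.05. At that unadjusted p, too, the lists given here with 0 lower genes had 0 lower and the general stress list 0 higher. In the lists too small for camera, 1 of 4 GPI anchor synthesis genes (SPT14), 1 of 3 PIR genes (PIR3) and 1 of 3 O-mannosylation genes (KTR2) were higher. SPT14 had values on only 3 arrays, and its duplicate spots lay apart (mean SD 0.80). Adjusted over the list alone, all 3 PIR genes, which also belong to the integrity response list, were higher. The counts of the others in this paragraph did not change. SPS22, ALG9 and SPT14 were named after their values were seen.

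Further genes with large changes belonged to none of the lists. FLC2, which encodes a membrane protein of the flavin carrier family, had a log2 ratio of 2.09 ± 1.03 (4.27-fold; limma adjusted p = 0.0217), and lost the call without array 1, 2 or 3. The duplicate spots of FLC2 lay apart, with a mean SD of 0.60 over the arrays, against a median of 0.06 over tested genes. CHA1, the gene of a serine and threonine deaminase, rose 2.69-fold with an SD of 0.05 (log2 1.43). HIT1 had a log2 ratio of -1.07 ± 0.64, DCG1 of -0.79 ± 0.36 and URA7, a CTP synthase gene, of -0.74 ± 0.32. These 3 passed (limma adjusted p = 0.0463, 0.0289 and 0.0289) and each lost the call when any of at least 3 single arrays was left out.

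Arrays of the same channel order resembled each other more than arrays of opposite order. Across genes, which are not independent replicates, Pearson's r was 0.73 between arrays 1 and 3 and 0.75 between arrays 2 and 4, against 0.26 to 0.44 for the 4 pairs of opposite order. The coefficient for channel order passed for 23 genes (limma adjusted p under 0.05, 17 higher in the order of arrays 1 and 3 and 6 lower). The median SD over the arrays was 0.28, against 0.06 between duplicate spots on an array.

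**Figure D3:**
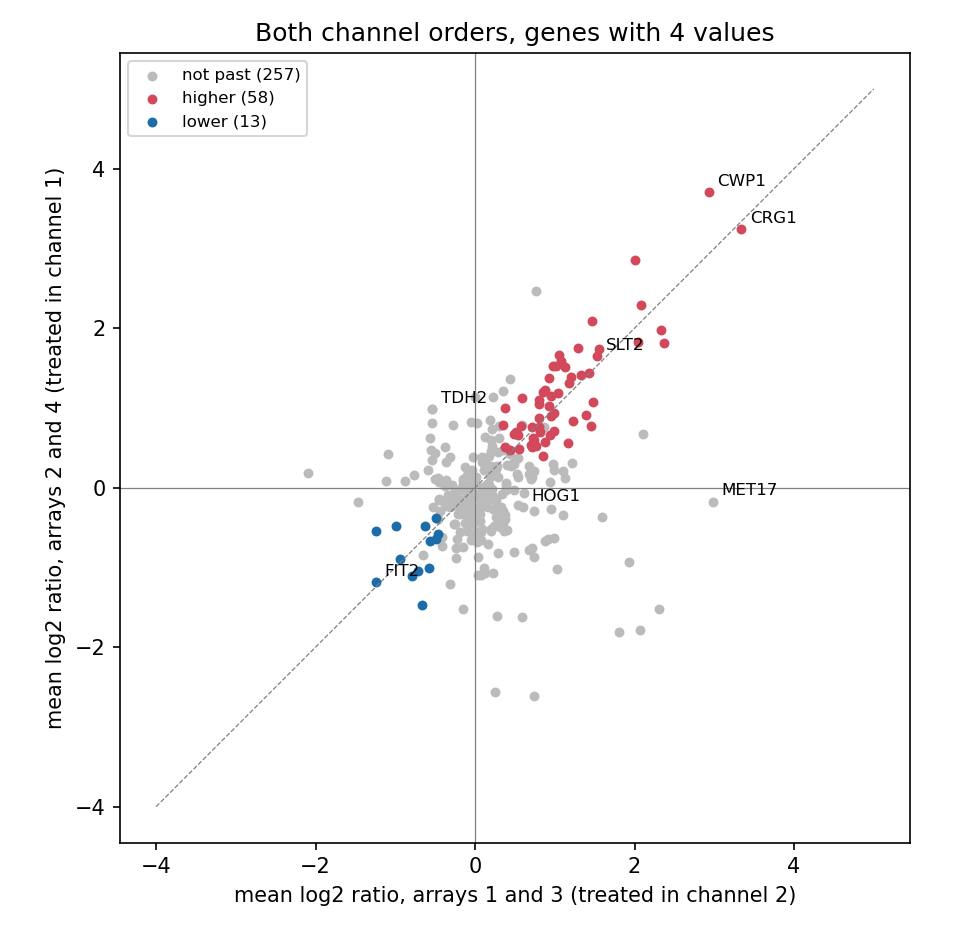
Mean log2 ratio on arrays 1 and 3 (x axis) against arrays 2 and 4 (y axis) for the 328 genes with values on all 4 arrays, with the 58 called higher, the 13 called lower and the 257 others in separate colours. Called genes follow the dashed line of equality, which the test favours by asking for little spread over these same arrays. MET17 and TDH2, labelled after their values were seen, lie far from it.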

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

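The tests of spot brightness, of a shared RNA extract, of turning, of random lists and of centring were chosen after the result was seen, and that of duplicate spots before, except for its repeat without genes of repeated ratio. Among 46 results with a value on every array (32 named genes and 14 lists), a single array stood far from the other 3 in 2. SLT2 had a log2 ratio of 1.42 on array 1, below the others by most of its range. The high osmolarity signalling list had a mean of -0.12 on array 2. That list includes the deleted gene HOG1, at -1.73 on array 2, and was not examined without it. The low mean therefore cannot be read as a result about the pathway. Chance alone marks about 1 in 20 such groups. Among spots with no gene name here, which entered the rule on direction but no gene or list test of the report, 7 were higher and 2 lower of 122 tested (limma adjusted p under 0.05), and 22 had an unadjusted p under 0.05. These are counts of spots, not of probes. All 362 odd-numbered spots with a gene name were followed by a spot of the same gene. The higher spots include 445 with 446, 757 with 758 and 85 with 86, so they may stand for fewer probes. The highest was spot 445, at a mean log2 ratio of 3.58 over 3 arrays, and the lowest spot 571, at -2.11 over 4.

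Arrays of the same channel order agreed more closely than arrays of opposite order, and the tests leave the reason open. For noisy spots, correlations of same-order pairs exceeded those of opposite-order pairs by 0.26 among the 110 genes with the closest duplicate spots (95% bootstrap interval over genes 0.16 to 0.41), and by 0.17 (0.11 to 0.26) once genes with a repeated ratio were left out, the latter between the bounds of 0.1 and 0.2 set beforehand. For a channel bias that depends on brightness, channel order coefficients averaged -0.48 for 7 reference genes and 0.41 for 11 spore wall genes, a difference of -0.89, but the comparison is void because 5 of the 7 carry a ratio that repeats across genes, as spots at the scanner's ceiling could. An RNA extract shared by arrays of one order cannot be told apart from channel order, and MET17, deleted in BY4741 but with a probe of unknown position, had a coefficient of 1.58 (limma adjusted p = 0.00336), which does not separate them at other genes.

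Genes of the cell wall integrity response stood above the rest of the chip. A shift of whole arrays is argued against only as far as the median measures it. After each array was centred on its median, 16 of the list's 23 genes were called higher, as before. Centring moved the list's mean only from 1.14 to 1.09, so it could hardly have ended the calls. A normalization that depends on intensity was not tested. A channel bias unrelated to the list and independent between genes, taken for treatment because arrays 2 and 4 had not been turned, is argued against too: the mean of 1.14 over the 23 genes lay above the highest of 10000 random lists of that size (0.68; share 1e-04, the smallest they can give), although camera has adjusted p = 0.46 with an estimated correlation and 0.86 with a channel order term as well. A bias that the list's genes share, for example through brightness, stays open, since intensities were not analysed here, and MET17, deleted in the strain but with a probe of unknown position, does not decide with treatment values of 1.40 as deposited and 1.58 with those arrays turned. A response to Congo Red is the biological explanation that the design names, and was not tested apart from this.

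The 8 assignments of signs to the 4 arrays are too few for a share under 0.05. The assignment with all arrays as deposited called 72 genes (limma), the count being reached by 1 of the 8, and the highest of the others called 0. The other turning is among those others, and since the turning is unsettled, none of the 8 can be called the real one. Flipping the sign of an array moves any ratio shared by the arrays, from treatment or from channel bias, into the spread. The 0 calls of the others therefore say nothing about treatment.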

How the results depend on the processing

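The other turning of arrays 2 and 4 changed most. It left 0 genes higher and 0 lower and turned the sign of the cell wall integrity response list (-0.042), the GPI-anchored list (-0.037), the reference genes (-0.48, then called with camera adjusted p = 5.2e-06, 5 of these 7 genes having a repeated ratio) and 17 called genes among those named: CWP1 -0.39, YPS3 -0.43, PRM5 -0.10, GSC2 -0.31, PST1 -0.095, SLT2 -0.058, SED1 -0.23, CHA1 -0.0022, RLM1 -0.25, CRH1 -0.19, PIR3 -0.31, FKS1 -0.18, NCW2 -0.043, HIT1 0.40, HSP26 0.16, WSC4 0.17 and DCG1 0.21. It puts the treatment against the channel order, so these values are coefficients of channel order. The 0 calls come from the fit without a term for channel order, and with that term 23 genes would pass under this turning. Without a call under either turning, N-glycosylation (-0.057), polarity and actin (0.11) and ACT1 (-0.084) also changed sign. The general stress list stood at -0.041.

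Under the other settings no called gene among those named changed sign. HOG1 (-0.24 without array 1 and -0.18 without array 4) and ACT1 (-0.0063 after scaling) did, never past the threshold. Lower genes numbered 23 after centring, of which with the higher ones 67 of the 72 calls were kept, 30 after centring and scaling (70 kept) and 34 with a term for channel order (72 kept). Arrays 1 with 4 and 2 with 3 averaged gave 90 higher and 48 lower, with 69 of 71 testable calls kept, and 1 with 2 and 3 with 4 gave 67 and 17, with 62 kept. A 2-fold minimum left 30 and 2. Leaving out 1 array gave 33 to 46 higher and 3 to 6 lower, and 38 to 50 of the calls were kept. Without an array 8 named genes lost their call at least once (FLC2, SPS2, GFA1, HIT1, HSP26, TIR3, DCG1 and URA7), and CHS3 gained it without array 2 (log2 1.00). Named genes also lost calls with arrays 1 with 4 and 2 with 3 averaged (2 genes), with robust variance (1) and with spots tested singly (2). In each averaging of pairs 1 named gene gained a call. Without the 8 genes of repeated ratio, chosen after seeing the data, 60 were higher and 15 lower, and all 72 calls were kept. Without genes of discordant duplicate spots, likewise chosen after seeing the data, 56 were higher and 15 lower. FLC2 and SPT14 were among the genes left out there, and all 63 testable calls were kept. Fewer arrays leave fewer degrees of freedom; for the other settings the cause was not tested.

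With an estimated correlation the integrity response (1.17), GPI-anchored (0.53) and general stress (-0.44) lists lost their calls, also together with a channel order term (adjusted p = 0.86 for each), chosen after seeing the data. The GPI-anchored list lost it with values on at least 2 arrays (0.48). The general stress list lost it after centring (-0.49), after scaling (-0.50), with either averaging of pairs, robust variance or values on at least 2 arrays (-0.44 each), and without array 1 or 3 (range over arrays left out -0.48 to -0.36). List calls gained under single settings (β-1,3-glucan, chitin and spore wall) and the lower spore wall mean without discordant duplicates stand beside those lists above. Cell integrity signalling, below the rest in camera, was above 0 in fry (0.12). Genes past the threshold for channel order numbered 49 after centring, 35 with robust variance and 46 without genes of discordant duplicates, the last chosen after seeing the data. The mean correlation of opposite orders was 0.35, and 0.40 over genes with 4 values. Centring moved the median of all genes from 0.02 to -0.04. Other logarithm bases were not run, since the values of arrays 1 to 3 settled base 2. For array 4 it rests on a similar spread. What the signal over background limits is unknown, as intensities were not analysed here.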

Other observations

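The tests below were chosen after the results were seen. Of the 72 genes called, 32 belonged to none of the lists, 26 higher and 6 lower, among 198 such genes tested. Besides FLC2, its relative FLC1 was higher (log2 0.74 ± 0.09, SD, n = 4; limma adjusted p = 0.00874). CMK2, a calmodulin-dependent kinase gene, had a log2 ratio of 0.87 ± 0.41 (limma adjusted p = 0.0289), and RIM21, a sensor gene of the alkaline pH pathway, 0.67 ± 0.20 (limma adjusted p = 0.0195). ERO1, needed for disulfide bonds in the endoplasmic reticulum, was lower (-0.62 ± 0.13; limma adjusted p = 0.0190).

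KDX1, which encodes a kinase related to Slt2, had values only on arrays 1 and 3, 4.26 and 4.79 on the log2 scale, and was not tested. It would have been the highest gene on the chip, and with values from a single channel order a channel effect could not be separated from treatment.

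A hypothesis was that genes called higher sit beside each other on the chromosome. Of 23 pairs of adjacent protein-coding genes with both members tested, 2 were higher at both (YPS1 with YPS3, and AFB1 with NFG1), against 0.65 expected when the calls were shuffled among tested genes (permutation test, one-sided, p = 0.135). Without the 7 pairs whose names share a stem, such as YPS1 and YPS3, 1 pair remained against 0.46 expected (p = 0.374, same permutation test). The pairs are too few to tell whether neighbours rise together or relatives share probe signal.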
